A study of Mus musculus with 54 samples.

How the data were processed

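RNA abundance was measured by sequencing of total RNA from 54 mouse libraries, brain and colon, of LRRK2 G2019S and WT mice kept germ-free or given P. goldsteinii. Per the labels' protocols, RNA was isolated with a column kit that yields DNA and RNA, and libraries were made after enzymatic removal of ribosomal RNA. Per the submitters' processing notes, reads passed through FastQC 0.11.9, cutadapt 3.5, STAR (version not given in the sources used here) and featureCounts 1.6.4 on the GRCm38 build. The deposited values are counts, that is raw read counts per gene, in 4 tables (brain and colon, 5M and 10M) with 1 column per library. All columns held whole numbers with totals that differed between libraries, as raw counts do. The annotation release and the strand setting are not given in the sources used here, although the names of the deposited tables hold the word reverse. Each table listed 55487 genes by versioned Ensembl identifiers, of which 55141 were given a name and 54435 matched the version of the reference annotation used for coordinates. The genes without a name held at most 0.054% of the counts.

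Groups were taken from the labels: tissue, time, genotype and treatment. In the titles WT is written NTG and LRRK2 G2019S is written HET. No column was left without a sample, and none was left out. The age, sex, housing and collection of the animals are not given in the sources used here beyond these labels.

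Each table was fitted on its own with R 4.3.3 and edgeR 4.0.16, using TMM factors, the filterByExpr filter over the 4 groups and a robust quasi-likelihood fit with 1 mean per group. This left 19164 genes in brain 5M, 19917 in brain 10M, 18970 in colon 5M and 17689 in colon 10M, with 99.8%, 99.9%, 99.5% and 99.9% of the counts. The biological coefficient of variation was 0.0852, 0.0936, 0.192 and 0.239. The 5 contrasts per table were LRRK2 G2019S against WT in germ-free mice and in mice given P. goldsteinii, P. goldsteinii against germ-free in each genotype, and their interaction. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested of a contrast. The adjustment ran within each contrast, not over the 20 contrasts. Contrasts within a table share libraries where they share a group. Means are TMM-scaled CPM with the SD over the libraries of the group. Differences between times were tested in a joint fit of both tables of a tissue.

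Gene lists, 45 in all, were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with the adjustment over all lists and contrasts of a table. Lists with fewer than 5 tested members were left out, which removed neutrophils, pancreas, and blood in brain 5M, and the sex-linked list served as a check. Beside each list call stands its adjusted p with the correlation estimated from the data. Counts of members past the threshold are given with the p adjusted over all genes tested and, where said, over the list alone. The samples, contrasts, lists, alternatives and the rule for named genes were fixed before the data were examined. That rule named Lrrk2 in every table and, for each contrast, the 6 largest rises and the 6 largest falls among called genes with a mean of at least 1 CPM, leaving out unnamed gene models and sex-linked genes. Where fewer than 5 genes were called it named the 5 with the smallest p. For called lists it named up to 4 members with the smallest p, and for lists with called members but no list call up to 2. Some list members that this rule named are not reported here. Genes named outside this rule, after their values were seen, are Psme4 in germ-free colon at 5M, Gm28438, Manf, Pdia4, the other genes shared by both genotypes in brain at 10M, Igkv17-127, Igkj1, Ighj3, Scd2 and Zfp775 in colon at 5M, and the pituitary hormone genes. Gpr75, beside Psme4, was named outside it as well.

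Libraries were checked for sex with Xist (at least 100 CPM) and the Y-linked genes (at least 200 counts), for pancreas transcripts, for mitochondrial counts (2.14% to 4.28%, 1.09% to 2.36%, 4.70% to 8.67% and 4.11% to 7.50% of counts in brain 5M, brain 10M, colon 5M and colon 10M), and for duplicates by a chi-square per gene between libraries of a group. The lowest value of this measure was 2.05, where a copied library gives 0, and no duplicate was found. Brain and colon libraries of the same name had the same sex reading in 26 of 26 cases. Of 24 pairs of groups 1 had a correlation of deviations from the group means over 0.1 in every couple with the same number, LRRK2 G2019S germ-free and P. goldsteinii in brain 5M (0.101, 0.221 and 0.348, against -0.294 to 0.124 for other numbers). The numbers were taken to pair these 6 libraries, from the data and not from the labels, and the blocked values stand beside that contrast. This pair of groups was picked from the 24 by its own correlations, so the pairing may be chance. The block was fitted over all 12 libraries of the table, WT ones included. Both replicates 3 expressed the Y-linked genes, so sex may add to the last correlation, which was not tested.

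The procedure was tested on simulated counts with the libraries and trended spread of each table and 200 changed genes. Each gene took the spread of genes of like abundance, not its own. Genes were drawn independently of each other, with no structure of the samples such as sex or pancreas transcripts. Members of the lysosome list were also raised 1.2-fold and counted as changed. Recovery of genes changed 1.5-fold, 2-fold and 4-fold was 61.2%, 76.1% and 93.9% in brain 5M, 65.7%, 77.6% and 95.5% in brain 10M, 14.9%, 56.7% and 92.4% in colon 5M and 14.9%, 56.7% and 90.9% in colon 10M. False calls made up 7.10%, 6.63%, 2.65% and 3.54% of the calls, and 0 genes were called in a contrast without change. In brain the share of false calls lay above the threshold of 0.05. The simulation cannot show how structure among the real samples affects the calls. Changes under 2-fold in colon are thus mostly out of reach at this depth and spread.

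The alternatives tried were DESeq2 size factors in place of TMM, no low-count filter, the Wald test of DESeq2 1.42.0, the replicate number as a block, sex as a factor, and each library left out in turn, and for the lists also the estimated correlation and the fry test. Colon 5M was also fitted without the 2 libraries with pancreas transcripts, an alternative chosen after the data were seen. Other splits of the same libraries were refitted to count how often they gave as many calls.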

Results

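The series asked what Parabacteroides goldsteinii (strain MTS01 per the labels), a gut commensal bacterium, did to gene expression in brain and colon of mice with the G2019S form of LRRK2, a kinase whose G2019S form is a cause of inherited Parkinson disease. Total RNA was sequenced from 54 libraries in 16 groups, which crossed tissue (brain or colon), time (5M or 10M as labelled), genotype (LRRK2 G2019S or wild type, WT) and treatment (germ-free or P. goldsteinii). All groups of brain and colon at 5M held 3 libraries. Brain at 10M had 4 libraries in each WT group and 3 in each LRRK2 G2019S group, and colon at 10M had 4 in every group. The labels give replicate numbers only, so the p-values measure the spread between these samples, and whether brain and colon libraries came from the same animals is not given in the sources used here.

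Total counts are given per library in megareads, in the order of the replicate numbers. In brain at 5M they were 12.8, 13.7 and 14.5 in WT germ-free, 13.4, 11.7 and 14.9 in WT P. goldsteinii, 11.6, 12.3 and 13.2 in LRRK2 germ-free and 13.7, 13.8 and 12.6 in LRRK2 P. goldsteinii. Brain at 10M had 17.8, 20.8, 19.5 and 20.6 in WT germ-free, 26.8, 29.5, 27.5 and 25.4 in WT P. goldsteinii, 30.9, 30.9 and 20.9 in LRRK2 germ-free and 30.9, 30.2 and 26.7 in LRRK2 P. goldsteinii, so the depths of the WT treatment groups did not overlap. In colon at 5M they were 11.4, 11.2 and 11.5 in WT germ-free, 9.89, 11.2 and 12.7 in WT P. goldsteinii, 11.2, 11.9 and 11.3 in LRRK2 germ-free and 13.2, 10.7 and 11.2 in LRRK2 P. goldsteinii. Colon at 10M had 18.0, 17.2, 19.1 and 17.0 in WT germ-free, 17.4, 20.2, 16.8 and 15.5 in WT P. goldsteinii, 19.0, 18.5, 18.6 and 18.5 in LRRK2 germ-free and 14.6, 19.6, 20.5 and 17.3 in LRRK2 P. goldsteinii.

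Sex was read from Xist, which is transcribed from the inactive X chromosome, and from the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty. At 5M the Y-linked genes were expressed in replicate 3 of every group except WT germ-free, in which all 3 libraries of each tissue expressed Xist. In brain at 10M all 6 LRRK2 G2019S libraries expressed the Y-linked genes, against 1 of 4 WT germ-free and 2 of 4 WT P. goldsteinii libraries. In colon at 10M the Y-linked genes were expressed in 3 of 4 libraries of each LRRK2 G2019S group. Sex was thus unequal between genotypes, and between treatments within WT. Replicate 4 of the WT germ-free group at 10M expressed neither kind of gene in either tissue, with Xist at 0.485 CPM and Ddx3y at 0 in brain. Transcripts of pancreatic digestive enzymes took 1.19% of the counts (exact binomial 95% confidence interval, counting error only, 1.19% to 1.2%) in WT P. goldsteinii replicate 3 of colon 5M and 1.95% (1.94% to 1.95%) in LRRK2 germ-free replicate 1. In every other colon library this share was at most 0.00113%.

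Lrrk2 (ENSMUSG00000036273.15, chromosome 15, 91673175 to 91816120, GRCm38) was higher in LRRK2 G2019S than in WT brain at 5M. In germ-free mice it reached 160 ± 4.18 CPM (SD, n = 3) against 113 ± 7.94 (n = 3), a log2 fold change of 0.50 (adjusted p = 0.00204). With P. goldsteinii it was 162 ± 5.61 against 102 ± 6.16 CPM, a log2 fold change of 0.67 (adjusted p = 1.43e-05). All 3 LRRK2 G2019S libraries lay above every WT library in both contrasts, and both calls held in every alternative. In brain at 10M Lrrk2 was at 136 ± 4.72 against 121 ± 10.3 CPM in germ-free mice (log2 0.17, adjusted p = 0.889) and at 132 ± 7.89 against 109 ± 11.7 CPM with P. goldsteinii (log2 0.28, adjusted p = 0.245). The genotype effects at 10M and 5M differed by -0.32 (adjusted p = 1) and -0.40 (adjusted p = 0.386), which did not pass the test of the difference. In colon Lrrk2 was not called by genotype either, at 59.4 ± 6.29 against 67.1 ± 3.99 CPM germ-free and 85.5 ± 21.4 against 53.5 ± 13.9 CPM with P. goldsteinii at 5M (log2 -0.18 and 0.67, adjusted p = 0.813 and 0.245). At 10M colon Lrrk2 was at 23.9 ± 5.40 against 20.5 ± 6.64 CPM germ-free and 22.1 ± 7.66 against 19.3 ± 10.1 CPM with P. goldsteinii (log2 0.22 and 0.20, adjusted p = 0.933 and 1). P. goldsteinii did not give a called Lrrk2 difference in any of the 8 treatment contrasts.

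Psme4 (ENSMUSG00000040850.17, chromosome 11, 30771726 to 30880361), which encodes the proteasome activator PA200, fell in LRRK2 G2019S mice in 6 of the 8 genotype contrasts, and in all 8 every LRRK2 G2019S library lay below every WT library. In brain at 5M it was at 72.6 ± 1.39 against 138 ± 16.9 CPM germ-free (log2 -0.92, adjusted p = 2.41e-06) and 70.9 ± 4.69 against 131 ± 4.50 CPM with P. goldsteinii (log2 -0.89, adjusted p = 4.55e-06). At 10M in brain it was at 30.6 ± 2.36 against 60.8 ± 4.71 CPM germ-free (log2 -0.99, adjusted p = 8.06e-08) and 31.9 ± 2.43 against 56.2 ± 2.56 CPM with P. goldsteinii (log2 -0.82, adjusted p = 3.18e-06). At 10M in colon it was at 45.7 ± 4.25 against 97.3 ± 8.39 CPM germ-free (log2 -1.09, adjusted p = 0.000457) and 47.3 ± 8.31 against 99.1 ± 1.76 CPM with P. goldsteinii (log2 -1.07, adjusted p = 0.00063). In colon at 5M it missed the threshold, at 131 ± 2.37 against 230 ± 12.5 CPM germ-free (log2 -0.81, adjusted p = 0.0684) and 127 ± 24.4 against 256 ± 42.2 CPM with P. goldsteinii (log2 -1.01, adjusted p = 0.107). The germ-free contrast of colon 5M was chosen for this account after its values were seen. With P. goldsteinii in colon 5M Psme4 was called by DESeq2 (adjusted p = 3.31e-07), without the low-count filter (0.000191), and without WT P. goldsteinii replicate 3 (0.00738), LRRK2 P. goldsteinii replicate 3 (0.0052) or the 2 libraries with pancreas transcripts (0.0156). It was not called with DESeq2 size factors (0.0867), sex as a factor (0.0682) or the replicate block (0.151). Nor was it called without WT P. goldsteinii replicate 1 (0.483) or 2 (0.108), or LRRK2 P. goldsteinii replicate 1 (0.0989) or 2 (0.178).

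**Figure D1:**
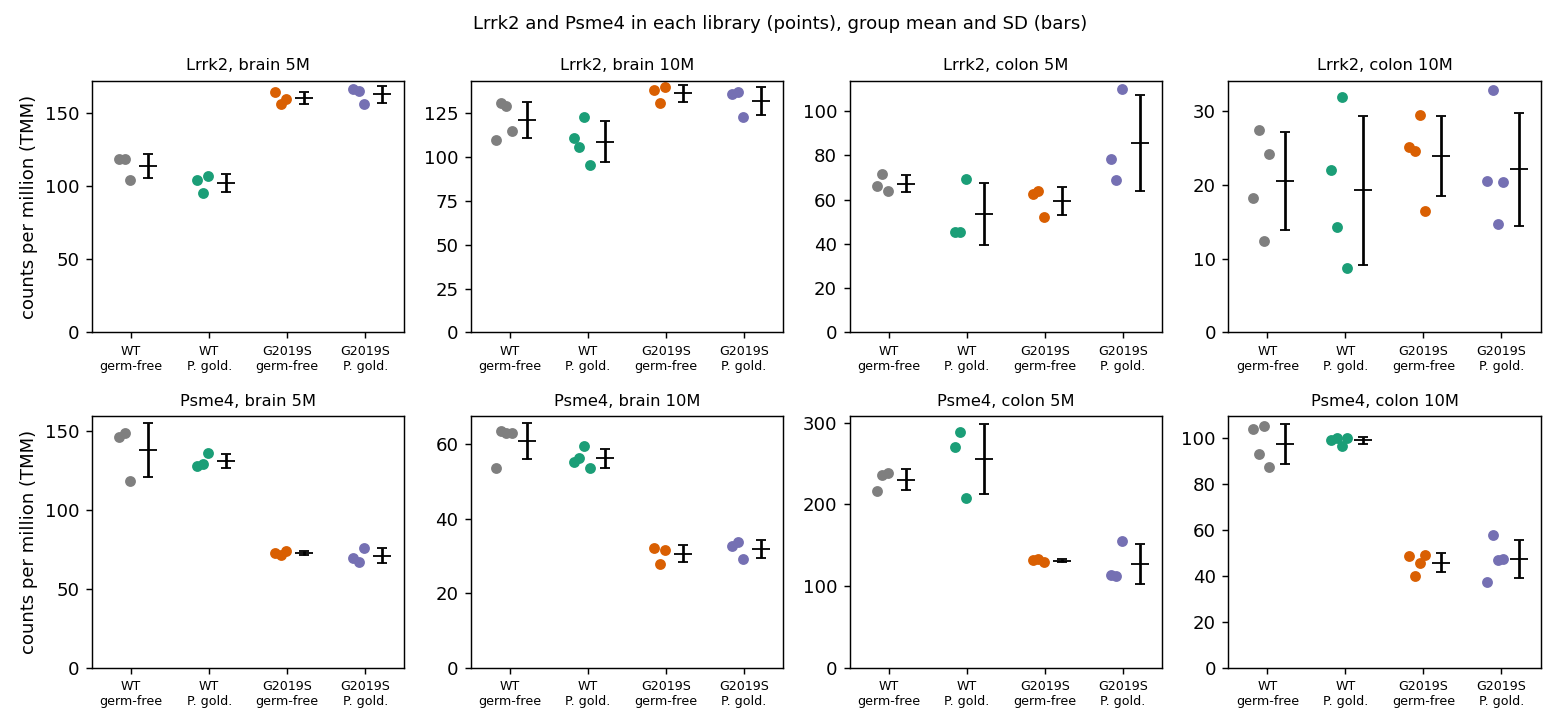
TMM-scaled CPM of Lrrk2 (upper panels) and Psme4 (lower panels) in each library of the 4 groups per tissue and time, with the group mean and SD beside the points. Psme4 lay between 47% and 57% of its WT level in LRRK2 G2019S mice in all 8 genotype contrasts, and Lrrk2 was higher in LRRK2 G2019S brain at 5M.

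The germ-free genotype contrast asks what the G2019S form changed in mice without bacteria. In brain at 5M, Lrrk2 rose and Psme4 fell, and no other gene was called among 19164 tested. The genes with the next smallest p were Hbb-bs, a beta globin (log2 0.80), F3, the coagulation tissue factor (0.39), and Gli2, a Hedgehog pathway transcription factor (-0.62), each with an adjusted p of 1. Homeostatic microglia genes as a list were called higher, with 16 of 20 members higher, a median log2 fold change of 0.17 and no member past the threshold (adjusted p = 0.00133; adjusted p = 0.786 with an estimated correlation).

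With P. goldsteinii 6 genes fell in LRRK2 G2019S brain at 5M, and each lay below all germ-free libraries in all 3 treated libraries. Tcf7l2, a Wnt pathway transcription factor strongly expressed in thalamus, fell by 0.58 on the log2 scale, from 84.5 ± 2.15 to 56.6 ± 5.54 CPM (adjusted p = 0.00435). Shox2, a homeobox transcription factor, fell by 0.76 (23.5 ± 1.09 to 13.9 ± 1.63 CPM, adjusted p = 0.0067), and Plekhg1, a guanine nucleotide exchange factor, fell by 0.58 (130 ± 2.60 to 87.1 ± 9.71 CPM, adjusted p = 0.00435). Rora, a nuclear receptor, fell by 0.38 (360 ± 11.9 to 276 ± 25.9 CPM, adjusted p = 0.0353), Tmed5, a secretory pathway protein, fell by 0.49 (adjusted p = 0.0304), and Synpo2, an actin-binding protein, fell by 0.48 (adjusted p = 0.0329). Thalamic, midbrain and hindbrain neuron genes as a list were called lower, with a median of -0.32 over 18 members, of which 1 fell over all genes tested and 7 fell adjusted over the list alone (adjusted p = 2.19e-09; adjusted p = 0.203 with an estimated correlation). The dissected region is not given in the sources used here. Without single libraries the count ran from 2 to 8, with 2 genes without LRRK2 germ-free replicate 1 or P. goldsteinii replicate 1 and 3 without LRRK2 germ-free replicate 3 or P. goldsteinii replicate 2, and Plekhg1 and Tcf7l2 stayed called in every alternative. The replicate numbers were taken to pair these 6 libraries, which the labels do not state. With the replicate block 3 genes were called, Tcf7l2, Shox2 and Plekhg1 (adjusted p = 0.0227 each), while Tmed5 (0.0991), Rora (0.12) and Synpo2 (0.125) were not. DESeq2 called 10 genes, with 3 of the 6 named here among them.

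In WT brain at 5M no gene passed the edgeR test between P. goldsteinii and germ-free, and DESeq2 called 7 genes. An unadjusted p under 0.05 was held by 854 genes, fewer than the 958 expected by chance. The smallest p belonged to Egr1, a transcription factor induced by neuronal activity (log2 -0.47, 116 to 83.5 CPM, adjusted p = 0.137), Hist1h1c, a linker histone (0.62), Homer1, a postsynaptic scaffold (-0.38, adjusted p = 0.15), Csf1r, the receptor that microglia need for survival (0.44, adjusted p = 0.15), and Frmd6 (-0.41, adjusted p = 0.166). The homeostatic microglia list was called higher, with 19 of 20 members higher, a median of 0.38 and 7 members that rose adjusted over the list alone (adjusted p = 8.6e-16; adjusted p = 0.203 with an estimated correlation). Csf1r, Cx3cr1 (26.1 to 34.1 CPM) and Tyrobp (2.82 to 5.05 CPM) were higher in all 3 treated libraries. Immediate early genes as a list were called lower, with 18 of 22 members lower and Arc at 70.2 against 116 CPM (adjusted p = 5.84e-09; adjusted p = 0.786 with an estimated correlation).

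Among mice given P. goldsteinii, LRRK2 G2019S brain at 5M differed from WT in 6 genes. Besides Lrrk2 and Psme4, Egr1 rose to 132 ± 10.2 against 83.5 ± 1.33 CPM (log2 0.66, adjusted p = 0.000575), and Klf10, a transcription factor induced by TGF-beta, rose by a log2 of 0.67 (19.4 against 12.2 CPM, adjusted p = 0.0474). Frmd6 rose (log2 0.44, adjusted p = 0.0474) and Prkcd, a protein kinase C strongly expressed in thalamus, fell (log2 -0.53, 81.3 ± 8.70 against 117 ± 18.8 CPM, adjusted p = 0.0474). In each case all 3 LRRK2 G2019S libraries lay beyond every WT library. Frmd6 missed the threshold with sex as a factor, and the other 5 calls were kept. The same WT P. goldsteinii libraries had lower Egr1, Frmd6 and immediate early genes than WT germ-free mice, with no gene called by edgeR. Their rises in LRRK2 G2019S mice are thus not independent of that contrast. Immediate early genes were called higher as a list, with 20 of 22 members higher, 1 that rose over all genes tested and 6 adjusted over the list alone (adjusted p = 4.4e-17; adjusted p = 0.575 with an estimated correlation). Choroid plexus genes were called higher (adjusted p = 3.65e-07; adjusted p = 0.786 with an estimated correlation) and thalamic, midbrain and hindbrain neuron genes lower (adjusted p = 2.49e-06; adjusted p = 0.41 with an estimated correlation). The count ran from 3 to 8 without single libraries, and was 3 without WT P. goldsteinii replicate 1 or 3 or LRRK2 P. goldsteinii replicate 1 or 2.

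The interaction asks whether P. goldsteinii acted differently in the genotypes. In brain at 5M edgeR called 0 genes for it, and DESeq2 called 0. An unadjusted p under 0.05 was held by 660 genes, fewer than the 958 expected by chance. Prkcd (log2 -0.68), Plekhg1 (-0.55), Egr1 (0.56), Synpo2 (-0.55, adjusted p = 0.484) and Tcf7l2 (-0.50, adjusted p = 0.78) had the smallest p.

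In LRRK2 G2019S brain at 10M, genes of protein folding in the endoplasmic reticulum fell with P. goldsteinii. Hspa5 (ENSMUSG00000026864.13, chromosome 2, 34771970 to 34777547), which encodes the chaperone BiP, fell from 423 ± 64.7 to 244 ± 16 CPM (log2 -0.79, SE 0.09, adjusted p = 0.000148). Its partner cofactor gene Sdf2l1 fell from 19.3 ± 4.39 to 9.33 ± 1.06 CPM (log2 -1.04, adjusted p = 0.00035) and Creld2, a disulfide isomerase family member, from 19.7 ± 3.53 to 10.9 ± 0.861 CPM (log2 -0.85, adjusted p = 0.0015). Xbp1, a transcription factor of the unfolded protein response, fell by 0.61 on the log2 scale (adjusted p = 0.000731). In each case all 3 treated libraries lay below all 3 germ-free libraries. Of 21 members of the unfolded protein response and heat shock list 19 were lower, with a median log2 fold change of -0.56. Over all genes tested 8 members fell, with Pdia4 (-0.55), Manf (-0.56), Ddit3 (-0.63) and Dnajb1 (-0.61) besides the genes named, and 16 fell adjusted over the list alone. The list was called with an adjusted p of 1.26e-38, with an adjusted p = 0.0357 with an estimated correlation, and by the fry test with an adjusted p of 0.0122.

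Altogether 14 genes rose and 36 fell with P. goldsteinii in LRRK2 G2019S brain at 10M. The other large falls were of mt-Ti, a mitochondrial transfer RNA gene (log2 -1.23, 7.45 to 3.15 CPM, adjusted p = 0.0015), whose short transcript makes its count uncertain, of Klf4, a transcription factor (-0.90, 7.70 to 4.12 CPM, adjusted p = 0.0181), and of Serpinh1, the collagen chaperone HSP47 (-0.84, 20.8 to 11.6 CPM, adjusted p = 0.00286). The largest rises were of Myo5c, an unconventional myosin (0.90, 2.73 to 5.18 CPM, adjusted p = 0.0387), Heyl, a Notch target (0.66, 5.36 to 8.53 CPM, adjusted p = 0.0232), the kinase gene Hunk (0.53, 24.7 ± 1.58 to 35.7 ± 0.801 CPM, adjusted p = 0.000872), Cxcl12, a chemokine (0.51, 58.1 ± 11.3 to 83.3 ± 3.41 CPM, adjusted p = 0.0202), Ddit4l (0.51, 10.5 to 15.0 CPM, adjusted p = 0.0234) and Prkab1, a subunit of AMP-activated kinase (0.51, 10.1 to 14.4 CPM, adjusted p = 0.0336). All 22 immediate early genes were lower, of which Klf4 and Fosl2 (-0.59, adjusted p = 0.0234) fell, and the list's call had an adjusted p = 0.431 with an estimated correlation. Dopaminergic neuron genes were called lower (adjusted p = 9.87e-09; adjusted p = 0.346 with an estimated correlation), among which Nr4a2, the dopaminergic transcription factor NURR1, fell from 50.2 to 34.9 CPM (log2 -0.52, adjusted p = 0.0147). Slc6a3, the dopamine transporter, was at 14.4 against 20 CPM (adjusted p = 0.352). Reactive astrocyte genes were also called lower (adjusted p = 5.57e-06; adjusted p = 0.431 with an estimated correlation). Without LRRK2 germ-free replicate 1 the count was 77, without germ-free replicates 2 or 3 it was 33 and 13, and without P. goldsteinii replicate 2 it was 11.

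WT brain at 10M gave the largest count of the 20 contrasts, with 33 genes that rose and 136 that fell with P. goldsteinii (213 and 290 without the low-count filter, 124 and 321 by DESeq2). With sex as a factor, which differed between these groups, 115 genes were called, of which 106 were among the 169. Xbp1 fell from 96.9 to 68.0 CPM (log2 -0.51, adjusted p = 0.000965), Creld2 by 0.73 (adjusted p = 0.00248), Sdf2l1 by a log2 of 0.73 (17.6 to 10.6 CPM, adjusted p = 0.0032), and Hspa5 from 394 ± 36.4 to 289 ± 11.2 CPM (log2 -0.45, adjusted p = 0.00681). Manf (-0.41) and Pdia4 (-0.34) fell too, which made 6 of 21 members over all genes tested and 7 adjusted over the list alone, with a list median of -0.22 (adjusted p = 1.59e-11; adjusted p = 0.334 with an estimated correlation). The largest falls were of Noxred1 (-1.26, adjusted p = 0.0104), Plekhg4 (-1.06, adjusted p = 0.0164), Cd93, an endothelial receptor (-0.87, 11.1 to 6.05 CPM, adjusted p = 0.000433), Banp, a nuclear matrix protein that binds DNA (-0.87, 31.5 ± 3.28 to 17.3 ± 1.43 CPM, adjusted p = 4.2e-06), Nes, the intermediate filament nestin (-0.86, 19.5 ± 2.12 to 10.7 ± 1.36 CPM, adjusted p = 8.04e-05), and Klf4 (-0.79, adjusted p = 0.00949). The largest rises were of Tekt4, a ciliary microtubule protein (1.29, 1.14 to 2.77 CPM, adjusted p = 0.0222), Depp1 (1.24, adjusted p = 0.0435), Galnt15, a glycosyltransferase (1.10, 3.19 to 6.79 CPM, adjusted p = 0.00681), Arrdc2 (0.90, adjusted p = 0.0226), Paqr5, a membrane progesterone receptor (0.71, adjusted p = 0.0461), and Klhl40 (0.70, adjusted p = 0.046). For these 12 genes every treated library lay beyond every germ-free library.

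Further genes that fell in WT brain at 10M were the clock gene Per2 (-0.50, adjusted p = 0.0032), Nr4a2 (-0.43, adjusted p = 0.0131), Homer1 (-0.45, adjusted p = 0.0226), Slco1c1, a thyroid hormone transporter of the blood-brain barrier (-0.32, adjusted p = 0.0461), and the immediate early genes Fosl2 (-0.57, adjusted p = 0.00735) and Nr4a3 (-0.68, adjusted p = 0.0278). The immediate early gene list was called lower with 3 members that fell (adjusted p = 0.0322; adjusted p = 0.743 with an estimated correlation). The count ran from 48 to 280 without single libraries, with 280 without P. goldsteinii replicate 2, which held 11.4% of its counts in 10 genes, and with 108, 50 and 50 without germ-free replicates 2, 3 and 4. It was 67, 96 and 48 without P. goldsteinii replicates 1, 3 and 4. Cd93, Banp, Nes, Hspa5, Sdf2l1, Xbp1 and Creld2 stayed called in WT brain under every alternative.

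**Figure D2:**
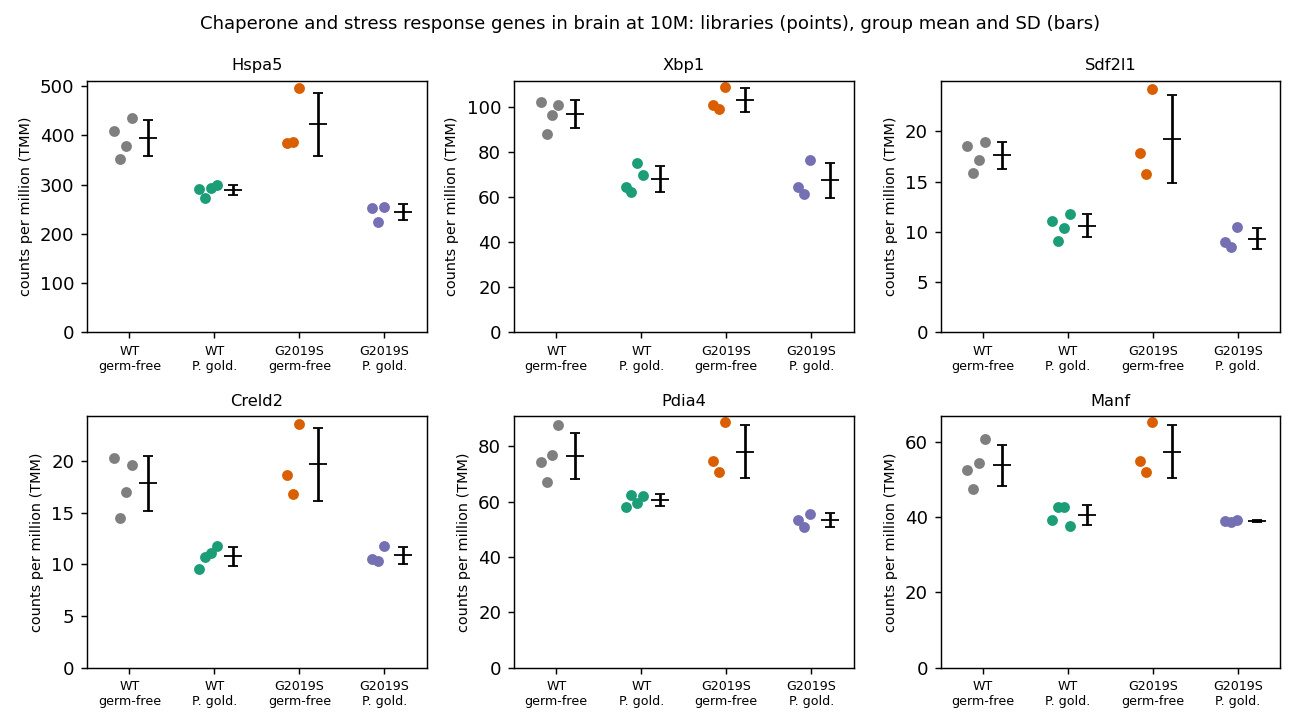
TMM-scaled CPM of Hspa5, Xbp1, Sdf2l1, Creld2, Pdia4 and Manf in each brain library at 10M, with the group mean and SD beside the points. Within each genotype the P. goldsteinii means lay below the germ-free means for all 6 genes, as for Hspa5 with 244 against 423 CPM in LRRK2 G2019S and 289 against 394 CPM in WT mice.

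The treatment contrasts of the genotypes share no library, so their called genes in brain at 10M can be set side by side. Of the 36 genes lower in LRRK2 G2019S and the 136 lower in WT mice 22 were shared, where independent lists would share 0.246 (Fisher's exact test over 19917 genes, p = 1.34e-39). Genes are not independent replicates, so this p overstates the evidence. Both contrasts also came from the same fit and share the spread estimate of each gene, which favours calls of the same genes in both. The shared genes included the chaperone and folding genes Hspa5, Sdf2l1, Creld2, Manf, Pdia4, Pdia6, P4ha1 and Serpinh1, and the transcription factor genes Xbp1, Creb3l2, Klf4, Fosl2, Nr4a2 and Rfx4. Maml3, a transcriptional coactivator gene, Banp, Hexim1, Inhba, Pfkfb3, Sik2, Slco1c1 and Spry4 completed them. Heyl, Hunk and Sh2d3c were shared among 14 and 33 higher genes. Of the genes called in LRRK2 G2019S mice 45 of 50 had the same sign in WT mice. Across all genes tested the correlation of the log2 fold changes was -0.0876.

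Between genotypes, brain at 10M held 1 called gene in germ-free mice and 1 with P. goldsteinii, Psme4 in both. DESeq2 called 3 and 60, and without the low-count filter edgeR called 24 and 336. The germ-free count was 3 without LRRK2 germ-free replicate 1, and the other was 2, 5 and 3 without WT P. goldsteinii replicates 1 and 2 and LRRK2 P. goldsteinii replicate 1. Next in germ-free mice came Fabp7, a glial fatty acid binding protein (log2 0.69, adjusted p = 0.207), Nes (-0.47), Pcdhb14 (-0.46) and Slc26a2 (-0.39, adjusted p = 0.799). All 15 choroid plexus genes were higher in germ-free LRRK2 G2019S mice, with Ttr, the transthyretin gene, at 384 against 255 CPM (list adjusted p = 7.95e-12; adjusted p = 0.334 with an estimated correlation). With P. goldsteinii, Ndufa5 (-0.42), Ctss, a microglial cathepsin (-0.45), Cox7b (-0.34) and Slirp (-0.43) followed Psme4, each with an adjusted p of 0.181. Antigen presentation genes of MHC class I were called lower in LRRK2 G2019S mice, with 13 of 15 members lower, a median of -0.76 and 9 that fell adjusted over the list alone (adjusted p = 3.87e-07; adjusted p = 0.431 with an estimated correlation). B2m, the light chain of MHC class I, was at 28.6 against 48.6 CPM (adjusted p = 0.255). Lists of interferon-stimulated genes (adjusted p = 2.48e-06; adjusted p = 0.381 with an estimated correlation), disease-associated microglia (5.5e-06; adjusted p = 0.334 with an estimated correlation) and homeostatic microglia (5.5e-06; adjusted p = 0.431 with an estimated correlation) were called lower too. All LRRK2 G2019S libraries here expressed the Y-linked genes, against 3 of the 8 WT libraries.

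In the interaction of brain at 10M 3 genes were called, among them Ndufa5 and Cox7b, which encode subunits of respiratory complexes. Ndufa5 went from 36.3 to 43.9 CPM with P. goldsteinii in WT and from 44.3 to 32.9 CPM in LRRK2 G2019S mice (interaction log2 -0.70, adjusted p = 0.0414). Cox7b went from 63.9 to 75.4 and from 75.7 to 59.7 CPM (log2 -0.58, adjusted p = 0.0414). The remaining gene was the unnamed model Gm28438 (-0.86), named after its values were seen. Galnt15 (-1.51), Cst3 (-0.50) and Rpl26 (-0.50, adjusted p = 0.0893) came next. All 42 oxidative phosphorylation genes were lower in the interaction, with 2 that fell over all genes and 15 adjusted over the list alone (adjusted p = 1.15e-17; adjusted p = 0.381 with an estimated correlation). The 3 calls were absent with sex as a factor, and every library left out moved the count. It was 15, 0, 0 and 1 without WT germ-free replicates 1 to 4, 0, 48, 0 and 0 without WT P. goldsteinii replicates 1 to 4, 282, 0 and 0 without LRRK2 germ-free replicates 1 to 3, and 10, 0 and 9 without LRRK2 P. goldsteinii replicates 1 to 3.

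In germ-free colon at 5M, 8 genes differed between the genotypes. Nts (ENSMUSG00000019890.4), the gut peptide neurotensin of enteroendocrine cells, rose to 24.7 ± 9.71 CPM in LRRK2 G2019S from 4.63 ± 1.62 in WT mice (log2 2.41, adjusted p = 0.0371). Cyp4b1, a cytochrome P450, rose to 46.4 ± 13.5 from 9.43 ± 2.39 CPM (2.30, adjusted p = 0.0498), Prkg2, a cGMP-dependent kinase, to 80.9 from 34.7 CPM (1.22, adjusted p = 0.0498), and Acaa2, an enzyme of fatty acid oxidation, to 115 from 61.9 CPM (0.90, adjusted p = 0.0371). Plk3, a polo-like kinase (-1.44), Slc20a1, a phosphate transporter (-1.06), Kyat1 (-0.98) and Myo5c (-0.69) fell, each with an adjusted p of 0.0371. All 3 LRRK2 G2019S libraries lay beyond every WT library for each of these genes. Cholesterol synthesis genes were called lower, with 19 of 19 lower and 9 adjusted over the list alone (adjusted p = 4.93e-10; adjusted p = 0.339 with an estimated correlation), and B and plasma cell genes lower (adjusted p = 2.93e-10; adjusted p = 0.422 with an estimated correlation). Enteroendocrine genes (adjusted p = 5.91e-07; adjusted p = 0.367 with an estimated correlation) and fatty acid oxidation genes (adjusted p = 8.32e-08; adjusted p = 0.339 with an estimated correlation) were called higher. With sex as a factor the count was 42, with all 8 among them. No call was left without any 1 of the WT germ-free libraries or of LRRK2 germ-free replicates 2 or 3, and without the 2 libraries with pancreas transcripts the count was 149.

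Of 134 immunoglobulin gene segments tested 9 rose with P. goldsteinii in LRRK2 G2019S colon at 5M. Iglv2 was at 60.6 ± 17.4 CPM against 0.0578 in germ-free mice (adjusted p = 0.00873), Iglc2 at 87.2 ± 15.9 against 1.24 CPM (0.0123), Igkv4-57 at 21.7 ± 7.01 against 0.204 CPM (0.00509), Igkv4-91 at 11.8 ± 1.39 against 0.142 CPM (0.00509), Ighv2-9-1 at 6.75 ± 5.83 against 0.0295 CPM (0.0346) and Igkv3-4 at 4.32 ± 0.60 against 0.118 CPM (0.042). The treated libraries lay above all germ-free libraries in 3 of 3 for each, and near-identical segments can share or lose reads. Igkv17-127, Igkj1 and Ighj3 rose as well, besides Scd2, a fatty acid desaturase (log2 0.81), and Zfp775 (0.95). Nts fell from 24.7 to 2.93 ± 0.426 CPM (-3.08, adjusted p = 0.00873), Cyp4b1 to 9.02 CPM (-2.35, adjusted p = 0.0346), Barx2, a homeobox transcription factor, to 0.612 CPM (-1.92, adjusted p = 0.0452) and Prkg2 to 35.7 CPM (-1.18, adjusted p = 0.044). The genotype contrast used the same LRRK2 germ-free libraries, so the opposite signs of Nts, Cyp4b1 and Prkg2 are not independent. The same holds for the opposite signs of the cholesterol synthesis and the B and plasma cell lists. Cholesterol synthesis genes were called higher, with 19 of 19 higher and 13 adjusted over the list alone, among them Lss, Hmgcs1 and Insig1 (adjusted p = 7.68e-15; adjusted p = 0.249 with an estimated correlation). B and plasma cell genes were called higher, with 5 that rose adjusted over the list alone and Igha, the heavy chain of immunoglobulin A, at 703 against 134 CPM (list adjusted p = 9.36e-11; adjusted p = 0.422 with an estimated correlation). Fibroblast and matrix genes were called higher with 14 of 14 higher (adjusted p = 8.41e-09; adjusted p = 0.339 with an estimated correlation), as were macrophage genes (9.02e-08; adjusted p = 0.422 with an estimated correlation) and proliferation genes (7.86e-08; adjusted p = 0.422 with an estimated correlation). The count of 15 was 1, 3, 4 and 7 without LRRK2 germ-free replicates 2 and 3 and P. goldsteinii replicates 2 and 3, and 73 without the 2 libraries with pancreas transcripts.

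In WT colon at 5M 1 gene passed the test, Ido1 (ENSMUSG00000031551.12, chromosome 8, 24584136 to 24597009), which encodes an enzyme that degrades tryptophan and rose with P. goldsteinii from 1.02 ± 0.249 to 5.98 ± 0.210 CPM (log2 2.54, 3 of 3 libraries above all germ-free libraries, adjusted p = 0.0307). Iglv2 was at 52.0 CPM against 0.731 germ-free (adjusted p = 0.058), Iglc2 at 81.9 against 3.65 CPM (adjusted p = 0.0732), Kyat1 at a log2 of -0.97 (adjusted p = 0.0732) and Car1, a carbonic anhydrase, at 1.63 (adjusted p = 0.131). Antimicrobial defence genes were called higher, with 1 that rose and 7 adjusted over the list alone (adjusted p = 7.06e-10; adjusted p = 0.158 with an estimated correlation). Reg3g, a bactericidal lectin, was at 9.19 against 0.983 CPM (adjusted p = 0.261). Interferon-stimulated genes were called lower, with 34 of 36 lower and 12 adjusted over the list alone, as with Rsad2 at 10.5 against 26.0 CPM (list adjusted p = 5.5e-15; adjusted p = 0.422 with an estimated correlation). Goblet cell genes were called higher (adjusted p = 1.24e-06; adjusted p = 0.158 with an estimated correlation) and adipose genes lower (8.59e-06; adjusted p = 0.509 with an estimated correlation). The count was 99 without WT P. goldsteinii replicate 3, which held pancreas transcripts, 0 without any 1 of the germ-free libraries or P. goldsteinii replicate 2, and 2 without P. goldsteinii replicate 1.

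Between genotypes with P. goldsteinii in colon at 5M, edgeR called 0 genes and DESeq2 called 145. An unadjusted p under 0.05 was held by 2150 genes, against 948 expected by chance. After Psme4 the smallest p belonged to Hsd3b2, a steroid dehydrogenase (log2 -1.50), Dkk3, a secreted Wnt pathway protein (0.84), Col1a2, a collagen chain (0.79), and Hist4h4, a histone (1.18), each with an adjusted p of 0.108. Fibroblast and matrix genes were called higher in LRRK2 G2019S mice (adjusted p = 9.42e-13; adjusted p = 0.249 with an estimated correlation) and so were proliferation genes (1.63e-10; adjusted p = 0.422 with an estimated correlation). The count was 74 without WT P. goldsteinii replicate 3 and 82 without the 2 libraries with pancreas transcripts. For the interaction edgeR called 0 genes, or 17 with sex as a factor, and DESeq2 called 109. An unadjusted p under 0.05 was held by 1551 genes, against 948 expected by chance. Prkg2 (log2 -2.08, adjusted p = 0.0506), Cyp4b1 (-3.63, adjusted p = 0.0594), Nts (-3.52, adjusted p = 0.0715), Car1 (-2.48, adjusted p = 0.0715) and Osr2 (-5.89, adjusted p = 0.111) had the smallest p. Without WT P. goldsteinii replicate 3 the interaction count was 351, and without both pancreas libraries 378.

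In colon at 10M, the immunoglobulin kappa segment Igkv13-84 (ENSMUSG00000076538.1, chromosome 6, 68939602 to 68940067) rose with P. goldsteinii in both genotypes, and this was the call of each contrast. It was at 4.37 ± 1.58 (n = 4) against 0.171 CPM in LRRK2 G2019S mice (adjusted p = 0.0118) and at 2.76 ± 1.49 (n = 4) against 0.0302 CPM in WT mice (adjusted p = 0.00872), with 4 of 4 treated libraries above all germ-free libraries. Both calls were lost without any 1 of germ-free replicates 1, 2 or 3 of the genotype. In LRRK2 G2019S mice Igkv17-121 (adjusted p = 0.271), Tom1 (log2 0.56, adjusted p = 0.434), Ighv1-2 (adjusted p = 0.481) and Igkv4-72 (adjusted p = 0.666) came next. In WT mice they were Igkv4-72 (69.0 against 1.44 CPM, adjusted p = 0.135), Txlng (-0.65), Gsta3, a glutathione transferase (1.23, adjusted p = 0.158), and Tmem33 (-0.58, adjusted p = 0.187). With P. goldsteinii Igha was at 4050 against 1300 CPM germ-free in WT and at 3590 against 1580 CPM in LRRK2 G2019S mice, and neither difference was called.

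The cholesterol synthesis list was called higher with P. goldsteinii in LRRK2 G2019S colon at 10M, with 7 members that rose adjusted over the list alone and Mvk, mevalonate kinase, at 38.8 against 22.5 CPM germ-free (list adjusted p = 1.37e-23; adjusted p = 0.307 with an estimated correlation). Proliferation genes were called lower (8.81e-17; adjusted p = 0.336 with an estimated correlation), and unfolded protein response and heat shock genes lower with 5 that fell adjusted over the list alone (1.56e-08; adjusted p = 0.336 with an estimated correlation). The heat shock gene Hsph1 was at 41.9 against 116 CPM and Hspa5 at 447 against 690 CPM, and neither was called. Clock genes were called higher (3.54e-06; adjusted p = 0.124 with an estimated correlation). In WT mice interferon-stimulated genes were called higher (6.62e-07; adjusted p = 0.766 with an estimated correlation). B and plasma cell genes were called higher there as well (adjusted p = 0.0175; adjusted p = 0.766 with an estimated correlation), although the median of the list was -0.26 and its mean 0.14.

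Between genotypes in colon at 10M Psme4 was the called gene, germ-free and with P. goldsteinii. Germ-free, Knstrn (log2 0.79), Etv4 (0.89) and Ppp1r14b (0.48, adjusted p = 0.532) came next, then Col4a2 (0.47, adjusted p = 0.767). With P. goldsteinii, Irf9, a component of the interferon response complex (-0.93), the peptide transporter gene Tap1 (-1.10), Mus81 (0.42) and Gbp7 (-0.70) followed, each with an adjusted p of 1. Interferon-stimulated genes as a list were called lower in LRRK2 G2019S mice, with 36 of 36 members lower, a median of -1.38, none past the threshold over all genes and 33 adjusted over the list alone (adjusted p = 6.9e-52; adjusted p = 0.154 with an estimated correlation). Usp18 was at 2.87 against 16.3 CPM. The same WT P. goldsteinii libraries gave the higher interferon call against germ-free WT mice, so these calls are not independent. Over all genes of this contrast 284 had an unadjusted p under 0.05, fewer than the 884 expected by chance. MHC class I genes were called lower (adjusted p = 3.36e-24; adjusted p = 0.124 with an estimated correlation). In germ-free mice proliferation genes (4.22e-10; adjusted p = 0.558 with an estimated correlation) and adipose genes (2.94e-10; adjusted p = 0.336 with an estimated correlation) were called higher. In the interaction edgeR called 0 genes and DESeq2 called 2. An unadjusted p under 0.05 was held by 467 genes, fewer than the 884 expected by chance. Knstrn (-1.08), Slc6a9 (-0.63), Tent5b (-1.16), Trove2 (0.54) and Ccnb2 (-0.89) had the smallest p, each with an adjusted p of 1.

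**Figure D3:**
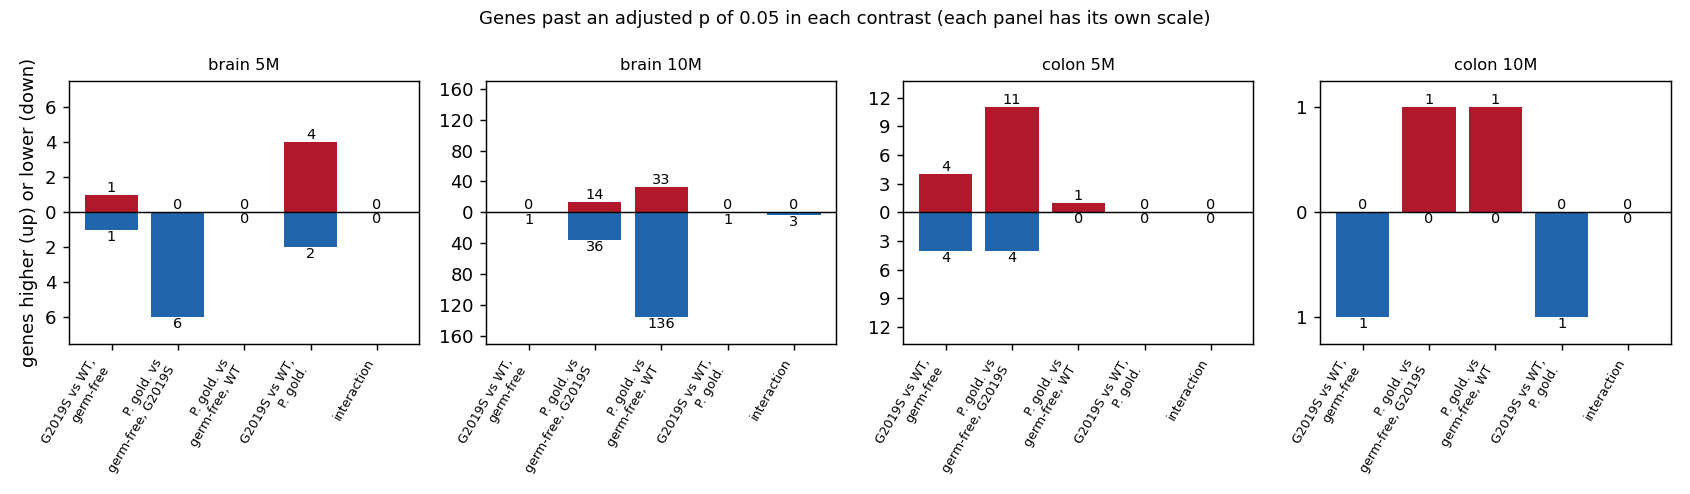
Number of genes past an adjusted p of 0.05 in each of the 5 contrasts of the 4 tables, with genes higher above the line and genes lower beneath it, each panel on its own scale. P. goldsteinii against germ-free in brain at 10M held the largest counts, with 50 genes in LRRK2 G2019S and 169 in WT mice.

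Over brain, 89 of 235 list tests were called with the preset correlation, and 1, the unfolded protein response list in LRRK2 G2019S mice at 10M, with an estimated correlation. Counted as called higher and called lower over the contrasts of both times, the lists gave 5 and 4 for homeostatic microglia, 2 and 3 for disease-associated microglia, 1 and 3 for reactive astrocytes, 1 and 5 for dopaminergic neurons, 0 and 4 for striatal neurons, 0 and 4 for synaptic transmission, 4 and 5 for immediate early genes, 1 and 2 for oligodendrocytes, 0 and 0 for brain endothelium, 1 and 0 for mural cells and meninges, 4 and 2 for choroid plexus, 0 and 0 for cortical and hippocampal neurons, 0 and 4 for thalamic, midbrain and hindbrain neurons and 0 and 3 for hypothalamic peptides. They gave 1 and 0 for blood, 2 and 2 for lysosome, 0 and 0 for LRRK2 substrates and Parkinson disease genes, 5 and 3 for oxidative phosphorylation, 1 and 0 for clock genes, 1 and 4 for the unfolded protein response, 0 and 3 for inflammatory cytokines, 1 and 2 for interferon-stimulated genes, 1 and 2 for MHC class I and 1 and 2 for MHC class II.

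Over colon 130 of 270 list tests were called with the preset correlation and 0 with an estimated correlation. In the same order of higher and lower, the lists gave 3 and 1 for antimicrobial defence, 3 and 0 for goblet cells, 0 and 6 for junctions, 2 and 3 for absorptive colonocytes, 0 and 0 for stem cells, 4 and 3 for proliferation, 1 and 3 for enteroendocrine cells, 3 and 0 for enteric neurons and glia, 6 and 1 for smooth muscle, 5 and 3 for fibroblasts, 4 and 1 for B and plasma cells, 2 and 4 for T and innate lymphoid cells, 4 and 3 for macrophages and 4 and 4 for adipose tissue. They gave 4 and 2 for xenobiotic and aryl hydrocarbon receptor targets, 2 and 5 for fatty acid oxidation, 7 and 1 for cholesterol synthesis, 0 and 1 for Toll-like receptor signalling, 0 and 0 for inflammatory cytokines, 1 and 8 for interferon-stimulated genes, 3 and 4 for MHC class I, 2 and 2 for MHC class II, 0 and 1 for lysosome, 0 and 0 for LRRK2 substrates and Parkinson disease genes, 6 and 0 for oxidative phosphorylation, 2 and 2 for clock genes and 2 and 2 for the unfolded protein response.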

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

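The tests of sex, of the Lrrk2 level and of the loss of 1 copy for Psme4, and those of sex and of time of day for the unfolded protein response genes, were chosen only after the results were seen. So were the fits of colon 5M without the 2 libraries with pancreas transcripts.

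Psme4 stood at 47% to 57% of its WT level in LRRK2 G2019S mice in both tissues and at both times, and unequal sex, a change of the whole region or a response to the Lrrk2 level could have produced this. With sex as a factor the smallest of the 8 falls was -0.76. Other genes within 1 Mb had a median of -0.007 over both tissues, with 0 of 15 called. These values argue against unequal sex and, for the region as a whole, against a change of the region. In colon at 10M Psme4 fell by 1.07 or more on the log2 scale where Lrrk2 differed by 0.22 and 0.20. The 95% intervals of Lrrk2 there (-0.55 to 0.99 and -0.57 to 0.97) included its rises in brain at 5M (0.50 and 0.67), so they cannot decide. In germ-free colon at 5M Lrrk2 was at -0.18 (-0.576 to 0.225) and Psme4 at -0.81 (-1.12 to -0.50, not called). That argues against a fall that needs an Lrrk2 rise as large as in brain at 5M. Loss of 1 of the 2 copies of Psme4 predicts a log2 fold change of -1, and 7 of 8 of the 95% intervals included it. The exception was brain at 10M with P. goldsteinii (-0.82, -0.97 to -0.66). Widened for 8 contrasts that interval also included -1 (-1.05 to -0.59), so loss of 1 copy stays open; an earlier bound, also set after the values were seen, had counted any single miss at 95% against it. Gpr75, the gene beside Psme4, was not called and lay at -0.09 to 0.14 in brain but at -1.07 to -0.60 in colon, with a mean of 0.517 CPM at 10M, so a change beyond Psme4 stays open in colon; an insertion of a transgene at the locus, a linked variant of the strain and an effect of the G2019S protein were not tested, since counts per gene cannot separate them.

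With P. goldsteinii in brain at 10M 8 of 21 unfolded protein response and heat shock genes fell in LRRK2 G2019S mice and 6 of 21 in WT mice, where the list call was lost with an estimated correlation (adjusted p = 0.334) and the depths and sexes of the treatment groups differed too. In LRRK2 G2019S mice all 6 libraries expressed the Y-linked genes, which argues against sex imbalance there. With sex as a factor 8 of 8 called members stayed called, which adds no evidence because sex did not vary in that contrast. In WT mice 5 of 6 members stayed called with that factor, which argues against sex imbalance for those 5. After removal of a trend on transcript length and GC content the list median was -0.59 against -0.56 before, which argues against that trend. The clock score differed by 0.081 (95% interval -0.07 to 0.23) in LRRK2 G2019S and by 0.05 (-0.08 to 0.18) in WT mice. This argues against a shift in the time of collection that moves the score. A single score need not move with every shift, so other shifts are not ruled out. Per2 fell in WT brain, and the clock list was called higher in LRRK2 G2019S colon at 10M. A response to the bacteria stays open as a hypothesis, and so do the unequal depth of the WT groups, handling, housing and the interval to dissection, which the labels do not give and to which immediate early genes (lower in the same libraries) and chaperone genes may both respond.

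Replicate 4 of the WT germ-free group at 10M expressed neither Xist nor Y-linked genes, and a single X chromosome is a candidate explanation. Genes that escape X inactivation (Kdm6a, Eif2s3x, Ddx3x and Kdm5c) would then lie below the libraries that express Xist, and their mean was lower by a log2 difference of -0.43 in brain and -0.60 in colon. In brain it was 6.31 (log2 CPM), against 6.72 to 6.76 in 4 libraries with Xist and 6.20 to 6.37 in 9 with Y-linked transcripts. In colon it was 6.495, against 6.79 to 7.27 in 6 libraries with Xist. The 9 with Y-linked transcripts had 6.18 to 6.82 there, so these ranges overlapped. In both tissues the library lay within the range of those with Y-linked transcripts. Escape genes thus cannot separate a female with a single X from a male whose Y chromosome was lost or silenced. That was not tested and stays open, and the sexes of the animals are not given in the sources used here.

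The effect of P. goldsteinii on 4 unfolded protein response genes in LRRK2 G2019S brain differed between 10M and 5M by a test of the difference over 20731 genes: Xbp1 (-0.79, adjusted p = 0.0189), Sdf2l1 (-1.27, adjusted p = 0.0213), Manf (-0.76, adjusted p = 0.0213) and Creld2 (-1.15, adjusted p = 0.035). At 5M none of them was called, with log2 fold changes of 0.19, 0.23, 0.21 and 0.31, so they fell at 10M alone. For the other called members the difference did not pass, with adjusted p = 0.152 for Pdia4, 0.163 for Hspa5 (-0.96), 0.235 for Ddit3 and 0.552 for Dnajb1. In WT mice it passed for none of the 4 genes (adjusted p = 0.687 for Xbp1, Sdf2l1 and Creld2 and 0.775 for Manf). The times come from separate tables, so time and sequencing run are confounded, and so are time and sex, with the Y-linked genes expressed in 1 of 3 libraries of each LRRK2 G2019S brain group at 5M and in 3 of 3 at 10M.

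The effect of P. goldsteinii differed between genotypes in brain at 10M for Gm28438 (-0.858), Ndufa5 (-0.704) and Cox7b (-0.58) by the interaction test, but 0 genes were called with sex as a factor, 0 to 282 without single libraries, and 3 of 40 splits gave as many calls.

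Single libraries stood far from the other 3 of their group in 10 of 192 groups of 4 tested, where chance gives about 1 in 20. Those of brain 10M were Psme4 in WT germ-free replicate 1 (53.7 CPM, others 62.9 to 63.5), Chac1 in the same library (5.31, others 3.82 to 4.03), Slirp in WT germ-free replicate 2 (10.9, others 9.55 to 9.69), Atf4 in WT P. goldsteinii replicate 3 (64.0, others 57.4 to 58.2) and Nes in WT P. goldsteinii replicate 4 (8.69, others 11.2 to 11.6). Those of colon 10M were Ppp1r14b in LRRK2 germ-free replicate 3 (27.5, others 25.9 to 26.1), Tent5b in LRRK2 germ-free replicate 4 (10.8, others 5.47 to 6.31), Col4a2 in LRRK2 P. goldsteinii replicate 1 (158, others 144), Ighv1-2 in LRRK2 P. goldsteinii replicate 2 (21.6, others 3.47 to 6.17) and Trove2 in WT P. goldsteinii replicate 1 (25.1, others 22.2 to 22.5).

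Prss2, a trypsinogen gene of the pancreas, was at 1380 CPM in WT P. goldsteinii replicate 3 and 1940 CPM in LRRK2 germ-free replicate 1 of colon 5M.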

How the results depend on the processing

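The fits of colon 5M without the 2 libraries with pancreas transcripts were chosen only after the data were seen, and all other alternatives before. Counts are given in the order germ-free genotype, P. goldsteinii in LRRK2 G2019S, P. goldsteinii in WT, genotype with P. goldsteinii, and interaction. They were 2, 6, 0, 6 and 0 in brain 5M, 1, 50, 169, 1 and 3 in brain 10M, 8, 15, 1, 0 and 0 in colon 5M and 1, 1, 1, 1 and 0 in colon 10M, and an alternative counts as a change where its count is beyond 1.5 times these.

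With DESeq2 size factors all counts stayed within this bound. Without the low-count filter the changed counts were 21, 47, 76 and 13 in brain 5M (the last 4 contrasts), 24, 194, 503, 336 and 422 in brain 10M, 110, 85, 18, 46 and 50 in colon 5M, and 2 for P. goldsteinii in WT colon 10M. The DESeq2 Wald test gave 10, 7 and 14 in brain 5M (contrasts 2 to 4), 3, 164, 445, 60 and 148 in brain 10M, 187, 217, 65, 145 and 109 in colon 5M, and 12, 13 and 69 in colon 10M for the contrasts 1 to 3 with 2 for the interaction. Of the 10 in brain 5M, 3 were among the 6 main calls of that contrast. With sex as a factor the interaction of brain 10M gave 0, colon 5M gave 42, 24 and 4 in its contrasts 1 to 3 and 17 in the interaction, and P. goldsteinii in WT colon 10M gave 4. For the other 23 pairs of groups no pairing was assumed, as not every same-number couple had a correlation over 0.1. That bound was passed in 0 of 19 same-number couples of brain 10M, 8 of 24 of colon 10M and 2 of 18 of colon 5M. In colon 10M 30 of 72 couples with other numbers passed it too, so it cannot show there whether libraries are paired. In brain 5M the replicate block left 3 of 6 calls of P. goldsteinii in LRRK2 G2019S mice, where the numbers were taken to pair, and changed no list call of that contrast. The replicate block gave 9, 3 and 5 in brain 5M (contrasts 1 to 3) and 5 in its interaction, 103 for P. goldsteinii in WT brain 10M and 0 in the interaction there, and 5 for P. goldsteinii in WT colon 5M and 7 in its interaction. For the germ-free genotype contrast of colon 5M it gave 7, of which 2 were among the 8, and for the genotype contrast with P. goldsteinii in brain 5M 8, of which 5 were among the 6. For P. goldsteinii in LRRK2 G2019S colon 5M it gave 15, of which 9 were among the 15 main calls. Without the 2 libraries with pancreas transcripts colon 5M gave 149, 73, 94, 82 and 378. That fit also has fewer libraries, and for the other changes the cause was not tested.

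Without each library in turn the counts ran from 2 to 2, 2 to 8, 0 to 0, 3 to 8 and 0 to 1 in brain 5M, from 1 to 3, 11 to 77, 48 to 280, 1 to 5 and 0 to 282 in brain 10M, from 0 to 7, 1 to 16, 0 to 99, 0 to 74 and 0 to 351 in colon 5M, and from 1 to 1, 0 to 8, 0 to 2, 1 to 1 and 0 to 0 in colon 10M. The 282 came without LRRK2 germ-free replicate 1, and the 99, 74 and 351 of colon 5M came without WT P. goldsteinii replicate 3, which held pancreas transcripts. Fewer libraries lower the power of such a fit, and the cause of the counts that grew was not tested.

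List calls numbered 29, 60, 71 and 59 in brain 5M, brain 10M, colon 5M and colon 10M. With an estimated correlation they were 0, 1, 0 and 0, and with fry 0, 1, 0 and 0, so nearly all rest on the preset correlation. Without the filter they were 34, 71, 79 and 62, and without single libraries 24 to 43, 47 to 65, 65 to 78 and 49 to 66.

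Among the named genes no called one changed direction: over all alternatives 694 called values stayed called and 283 did not. Of values not called, 398 became called and 30 changed sign. In brain 10M between germ-free genotypes Nlrc5 was at -1.22 and at 0.034 with sex as a factor, Col1a2 ranged from -0.066 to 0.378 without single libraries, Kcnj8 from -0.036 to 0.392, Hspa1b from -0.043 to 0.564 and Hspa5 from -0.028 to 0.179. With P. goldsteinii in LRRK2 G2019S brain 10M Lrrk2 ranged from -0.075 to 0.003. In colon 5M Cd8a ranged from -0.099 to 1.359 with P. goldsteinii in WT mice and was -0.10 without the pancreas libraries, and in LRRK2 G2019S mice Ndufa1 ranged from -0.018 to 0.936 and Ndufs4 from -0.069 to 0.766. In colon 10M Lrrk2 ranged from -0.277 to 0.337 in the interaction (0.033 with the replicate block, 0.003 with sex as a factor), from -0.368 to 0.043 with P. goldsteinii in LRRK2 G2019S and from -0.448 to 0.142 in WT mice, and from -0.058 to 0.557 between genotypes with P. goldsteinii, where Acta2 ranged from -0.006 to 0.314 and Ctss from -0.313 to 0.033. None of these differences was called.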

Other observations

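The tests of splits were chosen before the results were seen, while the pituitary genes, the sets of immunoglobulin, B cell and plasma cell genes and the length test of oxidative phosphorylation genes below were chosen only after.

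In colon the immunoglobulin segments had positive log2 fold changes with P. goldsteinii in 129 of 134 tested in LRRK2 G2019S and 107 of 134 in WT mice at 5M, and in 141 of 170 and 135 of 170 at 10M. Over all genes tested 9 and 0 of them rose at 5M and 1 and 1 at 10M, and the set as a whole was not tested. The related list of B and plasma cells lost its calls with an estimated correlation (adjusted p = 0.422 in LRRK2 G2019S at 5M, and 0.647 and 0.766 in LRRK2 G2019S and WT at 10M). B cell surface genes took opposite signs in the genotypes, with medians of 2.17 and -1.30 at 5M and 0.55 and -0.51 at 10M and no member called, while plasma cell genes had positive medians in both, with no member called either (2.07 and 1.11 at 5M, 1.27 and 1.42 at 10M). Lymphoid follicles are patchy along the colon, so how much of them each piece held bears on the B cell surface genes, and this was not tested.

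The 42 oxidative phosphorylation genes of brain at 10M were called in opposite directions, with all 42 higher with P. goldsteinii in WT mice (adjusted p = 3.82e-09; adjusted p = 0.431 with an estimated correlation) and all 42 lower in LRRK2 G2019S mice (adjusted p = 1.45e-09; adjusted p = 0.431 with an estimated correlation). Germ-free LRRK2 G2019S mice started above germ-free WT mice for all 42 (adjusted p = 4.58e-13; adjusted p = 0.431 with an estimated correlation). These genes are short, and fold changes followed transcript length weakly (Spearman correlation -0.146 germ-free between genotypes, -0.0851 in WT and 0.0387 in LRRK2 G2019S mice with P. goldsteinii). After removal of a trend on length and GC content the list medians were 0.10, 0.11 and -0.12, against 0.11, 0.11 and -0.10 before. RNA quality beyond this trend was not tested. These contrasts share groups, so they are not independent accounts of the same genes.

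Pituitary hormone transcripts were uneven in brain at 10M, with Prl at 39.1 CPM and Gh at 15.1 CPM in WT P. goldsteinii replicate 3 and Pomc at 26.8 CPM in LRRK2 germ-free replicate 2. They were uneven at 5M too, with Prl at 37.3, 37.2 and 0 CPM in LRRK2 germ-free, 18.5, 7.45 and 2.23 in LRRK2 P. goldsteinii, 3.70, 1.30 and 2.81 in WT germ-free and 0.446, 16.9 and 0.811 in WT P. goldsteinii mice. Whether pieces of pituitary were taken along with these brains is not given in the sources used here. In brain 10M WT P. goldsteinii replicate 2 stood apart from its group, with a chi-square per gene of 78.5 to 83.1 to the other 3 libraries against 9.59 to 10.6 among them, and 11.4% of its counts in 10 genes. LRRK2 P. goldsteinii replicate 3 of colon 5M stood apart from the other colon libraries, with a median correlation of 0.949 and 22.1% of its counts in 10 genes.

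Other splits of the same libraries were counted for each result. In brain at 10M, P. goldsteinii in WT mice gave 169 genes, 1 of 35 splits gave as many, the real one, and the highest other gave 61, and that share is the smallest 35 splits can give and is not adjusted over the results tried. Without WT germ-free replicate 3 or 4 or WT P. goldsteinii replicate 4 the count was below 61, in fits with fewer libraries, so chance is not firmly excluded. In colon at 10M the real split gave 1 gene for the germ-free genotype contrast and for P. goldsteinii in each genotype, with 0 as the highest other in each and 1 of 35 splits as large. A single gene against 0 is too thin to exclude chance, and the Igkv13-84 calls were lost without any 1 of germ-free replicates 1, 2 or 3. In colon 5M the lists gave 71 calls with 67 as the highest other and 1 of 40 splits as large, but 65 to 78 without single libraries and 0 with an estimated correlation, so chance is not excluded for that count.

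Chance was not excluded for the other results with enough splits and at least 1 call. In brain at 10M the genotype contrasts gave 1 gene each, with 4 of 35 splits as large and 64 (germ-free) and 27 (P. goldsteinii) as the highest other, the interaction gave 3 genes with 3 of 40 and 11, and the lists gave 60 with 3 of 40 and 71. In colon at 10M the genotype contrast with P. goldsteinii gave 1 with 2 of 35 and 1, and the lists 59 with 9 of 40 and 67. In brain at 5M the lists gave 29 with 34 of 40 and 64. The interactions of brain 5M, colon 5M and colon 10M gave 0 calls, which any split equals (40 of 40 in each, highest others 7, 1 and 965), so their splits say nothing about chance. These splits count calls and do not test Psme4 by itself.

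With 3 against 3 libraries the 10 splits are too few for a share under 0.05. In brain at 5M the real values and highest others were 2 and 0 for the germ-free genotype contrast (1 of 10 as large), 6 and 66 for P. goldsteinii in LRRK2 G2019S (2 of 10), 0 and 1 in WT (10 of 10, as any split equals 0), and 6 and 8 for the genotype contrast with P. goldsteinii (2 of 10). In brain at 10M they were 50 and 0 for P. goldsteinii in LRRK2 G2019S mice (1 of 10). In colon at 5M they were 8 and 0, 15 and 0, 1 and 0 (1 of 10 each), and 0 and 1422 for the genotype contrast with P. goldsteinii (10 of 10, as any split equals 0).

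A split that calls several times the real count points to a structure of the samples. The 1422 genes of colon 5M set WT replicates 1 and 2 with LRRK2 replicate 3 against LRRK2 replicates 1 and 2 with WT replicate 3, all given P. goldsteinii. In that order mitochondrial counts were 6.76%, 7.28% and 8.67% against 5.45%, 4.99% and 5.02%. The share of counts in 10 genes was 14.5%, 15.1% and 22.1% against 13.3%, 12.9% and 12.6%. This difference between libraries cuts across the genotypes, and its bearing on the calls of that contrast was not tested. The 66 genes of brain 5M set LRRK2 germ-free replicates 1 and 3 with P. goldsteinii replicate 3 against the other 3, and among the 4 splits that part every same-number pair of that contrast the others called 0 genes. The 64 of brain 10M exchange WT replicate 1 and LRRK2 replicate 3 of the germ-free groups. The 965 of the colon 10M interaction and the 11, 7 and 27 above have no named source in the labels.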
